A study of Danio rerio with 4 samples.

How the data were processed

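The series measured 5-hydroxymethylcytosine (5hmC), the base that TET enzymes make by oxidising 5-methylcytosine, in DNA from zebrafish at 48 hours after fertilisation. Sonicated, denatured DNA was pulled down with an antibody to 5hmC and sequenced (hMeDIP), per the labels. The extraction protocol speaks of head DNA, while the tissue label reads embryo. Embryos had received a control morpholino or morpholinos against tet2 and tet3. Morpholinos are antisense oligonucleotides that block translation or splicing of a transcript. The labels name 4 libraries, which are 1 pull-down and 1 input of each group. The 2 pull-downs have a peak list each. The inputs entered only through the authors' peak calling.

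Bowtie2 2.2.6, MACS2 2.2.7.1 and deepTools are named in the submitters' processing notes, with the builds GRCz11 and danRer11. Their settings are not given in the sources used here. Each deposited list belongs to 1 sample record, and whether reads were pooled before peak calling is not given in the sources used here. Each list held 1 run name in its peak names. The 2 run names differ in form, and neither repeats its sample's label. The lists were assigned to groups by the sample records alone. Each row gives a position, a summit and 4 values. The deposited score was the −log10 q-value times 10, cut to a whole number. The fold enrichment deposited by the authors is a ratio of the pileup at the summit to the local background, each with 1 added. The deposited −log10 p-values and −log10 q-values come from the authors' peak caller. The fold is the authors' value. It was used to describe, rank, filter and match peaks within a list and, with the p-value, to solve the depth behind each list. Folds of single peaks were not compared between the lists, though 1 alternative cut both lists at the same fold.

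Coordinates are given 1-based in the files' build (GRCz11). Peaks on chromosomes 1 to 25 entered the comparisons. A peak was overlapped if it shared at least 1 bp with a peak of the other list (bedtools 2.31.1, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, Python 3.11.15). Chance overlap over whole chromosomes was described, for both shares, by 100 random placements of the tet2/3 morpholino list within its chromosomes. For the terminal and interior shares, chance overlap was the mean share overlapped after moving the tet2/3 morpholino list by 20 or 50 kb to either side (4 moves), and it was removed as (share − chance) / (1 − chance). The length of a chromosome was taken as the position of the last peak end on it. With 1 library per group no test between groups was possible, no p-value is given, and differences between groups have no replicate check. SDs over the 25 chromosomes describe spread within a library pair. The 95% confidence intervals (Wilson) cover counting error only, and neighbouring peaks are not independent.

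The depth behind each list was solved from the deposited fold and p-value, which together fix the pileup and the background of a Poisson model. All peaks of both lists were solved (100% within a relative misfit of 0.0001). On simulated data the method recovered the fragment number of 100% of 2000 peaks, both for an unscaled and for a scaled library. Fragment lengths were taken from the shortest interval in each list. Absolute depths assume 1 effective genome size for both lists.

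The named peaks were the 5 with the highest fold in each list, by a rule fixed before the data were examined, as were the overlap measures and the alternatives on threshold, overlap, sequences and list length. The comparison by distance from a chromosome end, the 2 Mb limit, the boundary on chromosome 4 and the 1 Mb windows were chosen after seeing the data. The planned comparisons by gene, by genomic feature and over 20 gene lists, BMP genes among them, were not run. They need an annotation of GRCz11, and the gene table at hand is of another assembly (GRCz12tu). For the same reason no peak is assigned to a gene here. Peak lists of DNA do not show whether the tet2 and tet3 morpholinos acted on their transcripts.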

Results

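5hmC was mapped at 48 hours after fertilisation in zebrafish injected with a control morpholino or with tet2 and tet3 morpholinos, with 1 pull-down per group. The title of the series places the experiment in a study of TET enzymes and BMP signalling. The comparison asks where 5hmC enrichment was called after knockdown of the enzymes that make this base. The control list was called at a background of 7.53 fragments with 222 bp fragments. The tet2/3 morpholino list was called at 2.81 with 132 bp fragments. By the solved values, its pull-down had been scaled by 0.474 to a shallower input, from a background of 5.94 before scaling. Before scaling, the tet2/3 morpholino pull-down held 45.0 fragments per kb and the control pull-down 33.9. At the scaling used for calling, the tet2/3 morpholino list was tested at 21.3 fragments per kb, 1.59 times below the control list. Its background pileup was 2.68 times lower, which also holds the difference in fragment length.

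Fewer 5hmC peaks were called after tet2/3 knockdown on every chromosome. The control list held 226591 peaks on chromosomes 1 to 25 and the tet2/3 morpholino list 80550, a ratio of 2.81. Among peaks with a −log10 q of at least 5 in both lists, the ratio was 4.94, and at a fold of at least 4 it was 2.38. Neither cut lies at equal enrichment in the 2 lists. A q-value depends on tested depth, and the fold adds 1 to unlike backgrounds. Control peaks covered 108.9 Mb, or 8.10% of the chromosomes, and tet2/3 morpholino peaks 28.7 Mb, or 2.13%. The median width was 394 bp in control and 285 bp in tet2/3 morpholino embryos, and the shortest interval 222 bp and 132 bp. The ratio of peak numbers was 2.82 ± 0.118 (SD, 25 chromosomes), from 2.59 on chromosome 13 to 3.07 on chromosome 9. Chromosome 4 had the lowest density in both lists, with 102.6 control and 38.0 tet2/3 morpholino peaks per Mb. Control density was highest on chromosome 11, at 196.3 per Mb, and tet2/3 morpholino density on chromosome 23, at 72.2 per Mb. Peak number depends on tested depth, and width and covered length also on fragment length, so these values do not measure the amount of 5hmC.

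**Figure D1:**
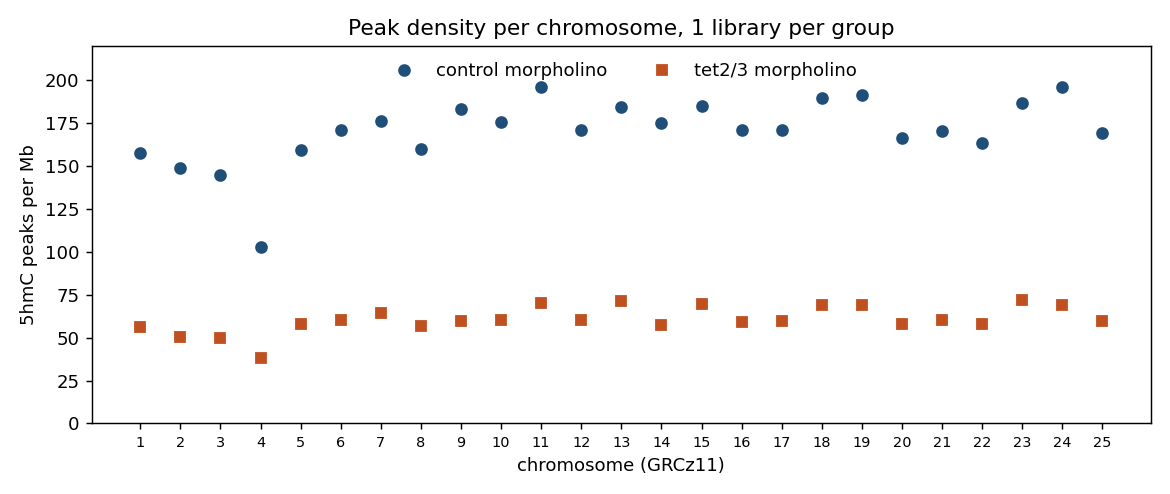
5hmC peaks per Mb (vertical axis) on each of the 25 chromosomes (horizontal axis) in the control and tet2/3 morpholino lists, 1 library per group. Control points lie above tet2/3 morpholino points on all 25 chromosomes, and both are lowest on chromosome 4.

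Most peaks called after knockdown shared at least 1 bp with a control peak. Of the tet2/3 morpholino peaks, 90.6% (95% CI 90.3 to 90.8) overlapped a control peak, against 14.0% for random placement. The share was 48.4% when 50% of both intervals had to overlap. Of the control peaks, 30.6% (30.5 to 30.8) were overlapped by a tet2/3 morpholino peak, against 4.94% for random placement. The control share varied little between chromosomes, with an SD of 1.27 points, from 28.1% on chromosome 14 to 33.2% on chromosome 23. In all, 157151 control peaks had no overlapping tet2/3 morpholino peak, and 7609 tet2/3 morpholino peaks had no overlapping control peak. When the control list was shortened to the number of the tet2/3 morpholino list by q-value, 58.0% of control and 62.2% of tet2/3 morpholino peaks were overlapped.

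Control peaks of high fold were overlapped more often. The overlapped share was 9.81% (9.56 to 10.1) at a control fold of 2 to 3, 31.5% (31.1 to 32.0) at 4 to 5 and 67.3% (66.7 to 67.8) at 6 to 8. It was 97.1% (96.0 to 97.9) at 12 or more, where 1233 of 1270 peaks were overlapped. Overlapped control peaks had a median fold of 5.39 and a median width of 581 bp, and the others 3.42 and 342 bp.

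The strongest peak of the control list, at chromosome 2:1966409-1967845, had a fold of 24.8 from 229 fragments and no overlapping tet2/3 morpholino peak. The second, at chromosome 12:44584979-44585818, had a fold of 24.0 and coincided with the strongest tet2/3 morpholino peak, at 44584984-44585693, with a fold of 18.4. The third, at chromosome 7:74041765-74044735, had a fold of 23.2 and was overlapped by 2 tet2/3 morpholino peaks with folds up to 6.64. The fourth, at chromosome 23:41031501-41032367, had a fold of 22.3 and met a peak with a fold of 12.9. The fifth, at chromosome 7:73940054-73940963, had a fold of 22.2 and met the fifth tet2/3 morpholino peak, at 73940172-73940809, with a fold of 16.3. The second tet2/3 morpholino peak lay at chromosome 14:26261-29040, with a fold of 17.5. The third lay at chromosome 8:53444117-53444552, with a fold of 17.3, and the fourth at chromosome 12:8671053-8672953, with a fold of 16.8. Folds of the 2 lists were made at different depths and are not compared.

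Control peaks near chromosome ends were overlapped more often than those in chromosome interiors. Within 2 Mb of an end, 49.6% (48.9 to 50.2) of 23432 control peaks were overlapped, and elsewhere 28.5% (28.3 to 28.7) of 203159. The difference of 21.1 points was positive on 25 of 25 chromosomes, with a mean of 21.2 ± 3.72 (SD), lowest on chromosome 3 at 12.4 and highest on chromosome 6 at 30.0. Terminal parts held 234.3 control and 147.8 tet2/3 morpholino peaks per Mb, a ratio of 1.59, and interiors 163.2 and 52.8, a ratio of 3.09. The share fell from 56.6% in the outermost 1 Mb to 40.9% in the next and 27.1% (26.8 to 27.5) at 10 to 20 Mb, and was 29.1% (28.7 to 29.5) at 20 to 40 Mb. Pooled over chromosomes, the share was 50.2% at the start and 48.9% at the finish. Single ends varied, from 41.0% on chromosome 24 to 62.4% on chromosome 22 at the start and from 37.4% on chromosome 14 to 60.9% on chromosome 1 at the finish. Tet2/3 morpholino peaks without an overlapping control peak were also more frequent near the ends, at 14.7% (14.1 to 15.2) of tet2/3 morpholino peaks against 8.27% (8.06 to 8.49) in interiors. Denser tet2/3 morpholino peaks give more overlap by chance near the ends. With that chance overlap removed, the shares were 39.8% and 23.2%, a difference of 16.6 points (SD 3.89), again positive on 25 of 25 chromosomes.

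**Figure D2:**
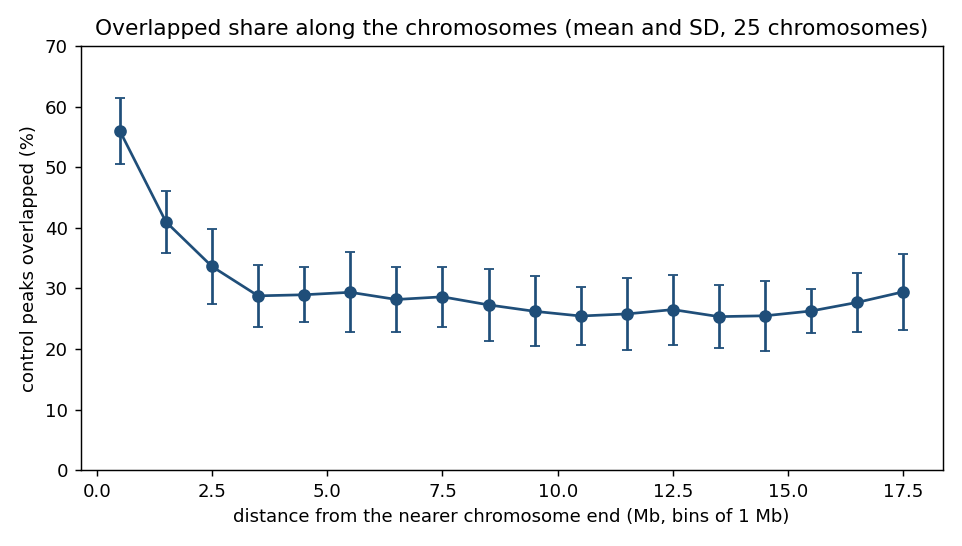
Share of control peaks overlapped by a tet2/3 morpholino peak (vertical axis, percent) by distance from the nearer chromosome end (horizontal axis, bins of 1 Mb). Points are means and bars SDs over the 25 chromosomes, with chance overlap not removed, and the outermost bin has a mean of 56.0%.

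**Figure D3:**
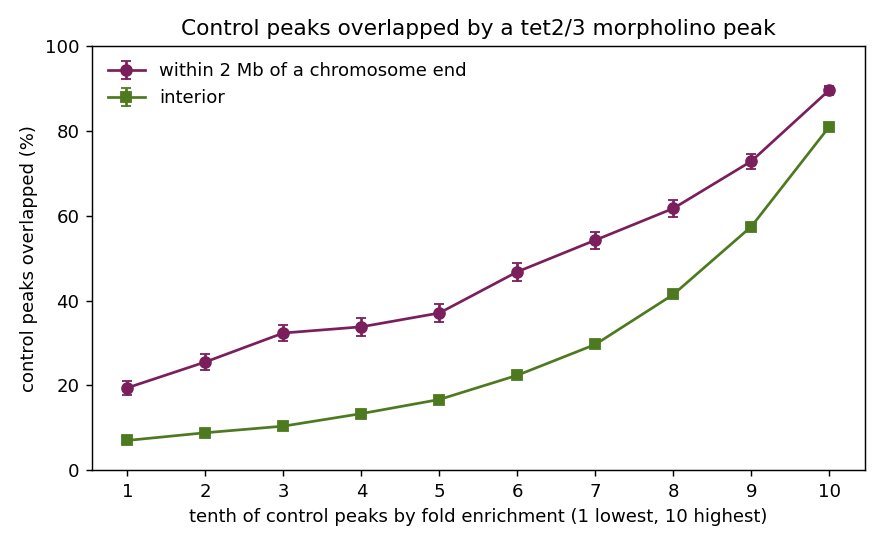
Share of control peaks overlapped (vertical axis, percent) in 10 bins of equal number by control fold (horizontal axis) within 2 Mb of a chromosome end and in the interior. Bars are 95% Wilson intervals, chance overlap is not removed, and the terminal share is higher in 10 of 10 bins. With chance overlap removed, the lowest bin has 7.72% and 2.70%, and the terminal share stays higher in 10 of 10 bins.

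Chromosome 4 differed along its length in both groups. From 30 Mb onwards it held 1331 control and 577 tet2/3 morpholino peaks in 48.1 Mb, a ratio of 2.31. The first 30 Mb held 6683 and 2388 peaks, a ratio of 2.80. The overlapped share of control peaks was 29.2% (26.8 to 31.6) from 30 Mb and 31.9% (30.8 to 33.0) before it. Of the tet2/3 morpholino peaks from 30 Mb onwards, 29.3% (25.7 to 33.1) had no overlapping control peak, against 5.82% (4.95 to 6.83) before 30 Mb and 9.41% on the other chromosomes. Control peaks were also sparser from 30 Mb, at 27.7 per Mb against 222.8 before it. Chance overlap was not removed from these shares.

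**Figure D4:**
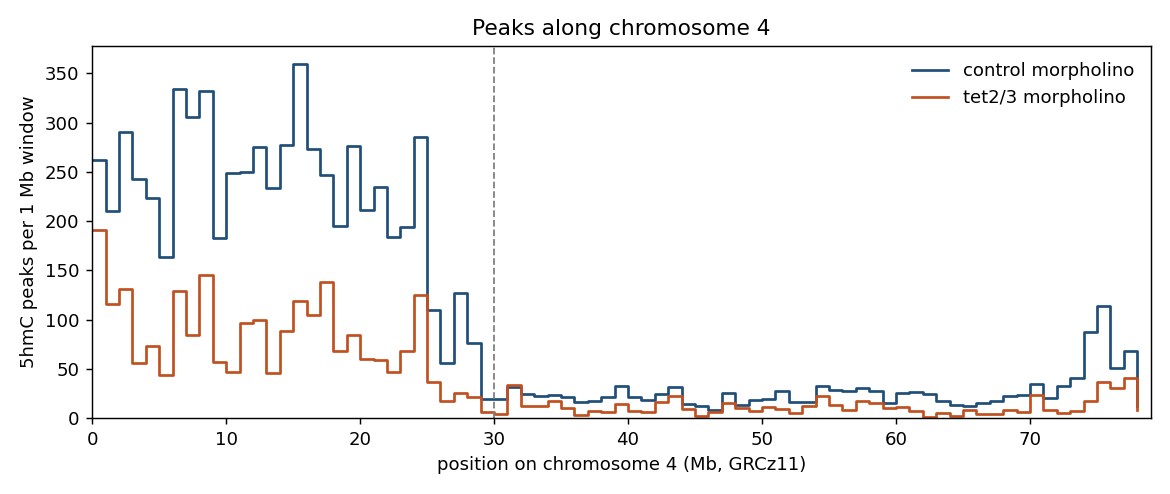
Peaks per 1 Mb window (vertical axis) along chromosome 4 in GRCz11 (horizontal axis, Mb) in the control and tet2/3 morpholino lists. The dashed line marks 30 Mb, after which both lists hold fewer peaks, 1331 and 577 in 48.1 Mb.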

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

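The tests on list size and on chromosome ends below were chosen after the results were seen, except the one that moves the tet2/3 morpholino list. Peaks outside the 25 chromosomes were left out of the comparisons, yet both lists held some, with 4012 control and 2153 tet2/3 morpholino peaks on unplaced scaffolds. There, 42.3% of control peaks (40.8 to 43.9) were overlapped.

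The control list was longer by 2.81 times. Lower tested depth does not account for the whole of it. Control peaks at the lowest background, strong enough to reach 2 times the lowest pileup of the tet2/3 morpholino list after scaling, were overlapped in 71.3% (SD over chromosomes 2.88), where 95% or more was required of depth alone. The tet2/3 morpholino background at missing peaks was not measured. A single factor of 0.472 on the excess over background was fitted to the total share. By control fold it gives 32.0% against 31.5% observed at a fold of 4 to 5. It gives too little for weaker peaks, with 1.85% against 9.81% at 2 to 3 and 9.75% against 17.1% at 3 to 4. For stronger peaks it gives too much, with 86.7% against 67.3% at 6 to 8. Chance overlap was not removed from the observed shares, so part of the shortfall for weaker peaks can be chance. At a control fold of 2.58 to 2.89, chance overlap was 4.48% in interiors and 12.8% near the ends. A lower 5hmC level after knockdown may underlie the loss, but a weaker pull-down could do so too. The 2 cannot be told apart with 1 pull-down per group, and strain or day of preparation were not tested for the same reason.

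Control peaks near chromosome ends were overlapped more often. Stronger control peaks there do not account for it, since a difference of 13.99 points (SD 4.66) was left at equal control fold with chance overlap removed. At equal control pileup and the lowest control background, 23.9 points (SD 6.64) were left with chance overlap removed. That match did not hold the tet2/3 morpholino background equal. It argues against 1 depth and 1 loss of enrichment for the whole genome only if that background was alike near the ends and in interiors. Moving the tet2/3 morpholino list by 20 or 50 kb left at most 9.77 of the 21.1 points, so chance overlap is a part and not the whole. A lower background near the ends in the tet2/3 morpholino input could be the cause and stays open.

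For that background, terminal peaks were overlapped as often as interior peaks with a control fold higher by 1.18 to 1.43 times over 9 bins of control fold. This was set against 3 bounds on what background could give, all tried after the values had been seen, and the outcome depends on which is used. The lowest of these ratios exceeded the interior over terminal background at called tet2/3 morpholino peaks (1.06) and the interior median over the lowest background (1.13), but not the interior mean over it (1.28). The deficit near the ends was not particular to the tet2/3 morpholino input, with a terminal over interior background of 0.947 there and 0.952 in control, and the control deficit is already in the control fold. Background was measurable only at called peaks, which are selected for a low one, so the explanation cannot be told apart from a smaller loss of 5hmC near the ends. Tet2/3 morpholino peaks without a control peak were also more frequent near the ends (14.7% against 8.27% in interiors). What either explanation predicts for these peaks was not tested. GC content was not tested, as no genome sequence was used here.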

How the results depend on the processing

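The alternatives on the terminal difference were chosen after seeing the data, and the others were planned. At a −log10 q of at least 5, the tet2/3 morpholino list fell to 38775 peaks, the ratio was 4.94, and the overlapped shares were 18.5% of control and 93.1% of tet2/3 morpholino peaks. At a fold of at least 4, the lists held 101801 and 42797 peaks, and the shares were 31.3% and 76.7%. With scaffolds included, the control share was 30.8%. An overlap of 50% of both intervals gave 17.2% and 48.4%, with a terminal difference of 15.1 points. A distance within 500 bp gave 34.1% and 93.0%, and lists of equal number 58.0% and 62.2%. The terminal difference was 27.5 points for 1 Mb, 11.7 for 5 Mb and 16.6 with chance overlap removed. Stricter thresholds lower the numbers by construction, and neither lies at equal enrichment in the 2 lists. A q-value depends on tested depth, and the fold adds 1 to unlike backgrounds. The median −log10 q was 5.09 in overlapped tet2/3 morpholino peaks and 8.32 in control peaks without overlap. The rule of 50% overlap can only lower the shares, and the distance within 500 bp can only raise them. A shortened control list can only lower the tet2/3 morpholino share. The cause of the other shifts was not tested. The ratio stayed between 2.38 and 2.79 under the 3 other alternatives. The terminal difference was positive on 25 of 25 chromosomes under each alternative run on all of them, and on 24 of 24 without chromosome 4. Results by gene, genomic feature and gene list were not run, nor were their alternatives. No paired analysis was possible because each group has 1 pull-down. Depth limits the weak peaks most: at the depth of the tet2/3 morpholino list, 77.1% of control peaks would be expected to pass.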

Other observations

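The tests on windows below were chosen after the result was seen, as were the peaks and windows named here. The longest control peak, at chromosome 4:6499075-6508445, spanned 9371 bp and held 5 tet2/3 morpholino peaks. Of the 1270 control peaks with a fold of 12 or more, 37 had no overlapping tet2/3 morpholino peak. Of these, 27 had one within 5 kb and 6 within 500 bp, and the number by chance was not computed. After the strongest control peak, the next control peaks without overlap lay at chromosome 9:6087820-6088215, with a fold of 18.4, and chromosome 23:15469289-15469683, with a fold of 14.7. The strongest tet2/3 morpholino peak without a control peak lay at chromosome 5:1854235-1854537, with a fold of 8.96. Away from the ends, control peaks with no other control peak within 10 kb were overlapped in 17.9% (21.2% expected from their fold), and those with 8 or more in 38.6% (34.5% expected). The expectation accounts for fold alone, and chance overlap with denser tet2/3 morpholino peaks was not removed here or in the windows below.

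The overlapped share also differed between 1 Mb windows of the interior. Over 1180 windows with at least 50 control peaks, the share minus that expected from control fold had an SD of 5.55 points. The highest of 100 shuffles gave 3.38. The spread is thus more than independent peaks would give, but local clustering of overlapped peaks would also raise it. Part of the spread restates the pattern at the chromosome ends, since the gradient runs past 2 Mb. Of the 6 windows furthest above expectation in units of counting error, 4 lay within 5 Mb of an end. At 10 Mb or more from an end, the SD was 5.12 over 793 windows, against 3.34 for the highest of 100 shuffles. Shuffling treats peaks as independent, and neighbouring peaks are not. On chromosome 25 from 9 to 10 Mb, 17 of 185 control peaks were overlapped (9.19%, 26.1% expected). On chromosome 18 from 5 to 6 Mb, 107 of 210 were (51.0%, 28.4% expected). Loss of 5hmC after tet2/3 knockdown may be uneven along chromosomes. Local differences in input background or GC content were not tested and stay open.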
